A study of Mus musculus with 42 samples.

How the data were processed

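MicroRNA (miRNA) levels were measured in total RNA from the livers of male B6C3F1 mice with single-colour Agilent arrays that hold 8 arrays on a slide. Per the labels, the RNA was isolated with a kit that keeps the small fraction, labelled with the cyanine dye Cy3 and hybridised. The slides were read with Agilent Feature Extraction 9.5.3.1, per the labels and the file headers. The deposited scanner files give a processed signal per spot in units of intensity, from which the software had subtracted background and a spatial trend, with no scaling between arrays. They also give the mean and median pixel intensity of each spot, its local background and a total signal per miRNA, again as deposited intensity values that were not scaled between arrays. A deposited table of values for all arrays holds log2 values, and no file states how they were made. Comparison with the scanner files showed that they were log2 median spot intensities without background subtraction, quantile normalized over the arrays of each time point, not centred and not expressed as ratios. The table has 15744 lines, of which 9891 hold values, and its line numbers were matched to array positions by their values: the correlation with the log2 median intensity at the matched position ran from 0.984 to 1.00 over the arrays. The remaining 1649 non-control spots have no value there. RNA integrity values, scanner settings and the reason for the storage classes are not given in the sources used here.

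Each array carries 11540 non-control spots for 1712 probes, with 5 to 20 spots per probe, and 577 miRNA names. Of these names, 567 are mouse miRNAs, kept as the files give them, and 10 are viral miRNAs, which were left out of every test. The arrays of mice killed at 24 h carry a later annotation in which 7 names of 19 probes differ, so the names on the 4 h arrays were used throughout. Coordinates are those in the files, on build mm9. No pair of arrays held identical values.

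The processed signals of a probe's spots were averaged without spots that the scanner software called outliers (1.92% to 5.45% of the spots of an array). Probe signals were divided by the array's 75th percentile over the 153 probes detected on all 42 arrays. A probe counted as detected when a share above 0.5 of its spots were well above background. Scaled signals were floored at 0.0174 of the 75th percentile, the probes of one miRNA were averaged on the linear scale, and the mean was taken to log2. A level of 0 therefore means a signal equal to the 75th percentile. For arrays their number limits the precision. There is no sequencing depth.

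Groups follow the labels: control and BaP mice at 4 h with RNA stored for under 7 days, the same with RNA stored for 6 to 8 weeks, control and BaP mice at 24 h, and 12 arrays of 1 pooled RNA. The pool arrays entered no comparison of animals except as a reference for their slide. BaP was compared with control by limma 3.58.1 in R 4.3.3 (linear fits with empirical Bayes variances, two-sided), and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All adjusted p values for single miRNAs come from limma, and values after ± in fold changes are its standard errors. Fits were made within the 4 h mice with each storage class, over the means of each 4 h animal's arrays on the log2 scale, within the 24 h mice, for the difference between the 24 h and 4 h effects, for storage with the animal as a block, and for the difference in BaP effect between storage classes. Tested miRNAs were those detected on at least as many arrays as the smaller group has. The main effect of time was left out, because the 24 h mice lie on a slide and scanner of their own.

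For storage, the animal is the pairing: the labels give the same animal for both arrays. Control and BaP mice that share a number were checked for pairing and left unpaired, since a BaP mouse's best match among controls had its own number in 2 of 6 cases for animal means at 4 h and in 0 of 2 at 24 h, although 5 of 6 and 1 of 2 same-numbered pairs correlated above 0.1 across miRNAs. The array of control mouse 5 labelled as stored for under 7 days lies on a slide with arrays of longer stored RNA, and it was kept with its label.

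Before the data were examined, 15 lists of miRNAs were fixed: p53 and DNA damage, hepatocyte, leukocyte, red blood cell, endothelial and mesenchymal (stellate), bile duct and epithelial, muscle, brain and pancreas, let-7 family, miR-17-92 and its paralogs, growth and injury, miR-29 and miR-30 families, lipid metabolism, the Dlk1-Dio3 imprinted cluster, and sequences that may be fragments of longer RNAs. The comparisons, the tests, the alternatives and the rule for naming miRNAs were fixed at the same time. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Lists with fewer than 3 tested members were counted and not tested. The naming rule took every miRNA past the threshold, the 5 with the lowest p in each direction, the 5 with the highest signal, the tested members of the p53 and hepatocyte lists, and the lowest and highest member of every other list. Names outside it are said to be chosen after their values were seen.

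Alternatives covered the probes behind the 75th percentile, quantile normalization, no scaling, cyclic loess, normexp background correction with an offset of 50, the brightest probe, the mean of log2 probe values, the total signal per miRNA, the deposited log2 values, a floor at 1% of the main one, 2 other detection filters, a trended robust prior, terms for slide and scan day, the ratio to the slide's pool arrays, a block for shared numbers, one fit of all groups, and leaving out each animal. Confidence intervals are at 95%. Permutation tests were exact over animals, or drew 100000 permutations for correlations over 11 animals. Other groupings of the same animals were drawn 100 times where more existed. The fits were tested on simulated data with the design and spread of each comparison and no slide effects, 20 runs each, with 10 miRNAs changed per fold size. Files were read with the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.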

Results

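Liver miRNAs were measured on 42 arrays. The mice were males of B6C3F1, a hybrid strain used in toxicology, labelled 27 to 30 days old and called adult in the series description. They received corn oil or 150 mg/kg benzo(a)pyrene (BaP) once a day for 3 days and were killed 4 or 24 h after the last dose. BaP is a polycyclic aromatic hydrocarbon of smoke and charred food that is metabolised in the liver to products that bind DNA. At 4 h, 12 mice (6 control, 6 BaP) were studied. RNA kept frozen for under 7 days was arrayed from 6 control and 5 BaP mice, and RNA of the same mice stored for 6 to 8 weeks was arrayed from 6 control and 6 BaP mice. At 24 h, 3 control and 4 BaP mice were studied with RNA stored for under 7 days. The remaining 12 arrays held 1 pooled RNA, labelled as stored for 6 to 8 weeks and repeated on the slides of the 4 h mice. The arrays detected 93 to 182 mouse miRNAs each (median 134.5), of which 89 were detected on every array. The 75th percentile intensity of an array ran from 332 to 1171.

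The highest signal came from the probes for miR-122, the main miRNA of hepatocytes, at a log2 level of 5.40 ± 0.24 (SD over the 30 animal arrays), which is 42.1 times the 75th percentile. It was followed by miR-720, a fragment of a transfer RNA, at 4.62 ± 0.38, and by miR-21, a miRNA linked to growth and injury, at 2.80 ± 0.32. Next came miR-22 at 1.89 ± 0.37, let-7f at 1.72 ± 0.16 and miR-192, an epithelial miRNA, at 1.63 ± 0.24. The red blood cell miRNA miR-451 stood at 1.42 ± 0.44. Different probes bind with different strength, so these signals do not rank the miRNAs by abundance. The probes for miR-122 are annotated to chromosome 18, 65408522 to 65408541 of mm9, with the strand listed as minus. Those for miR-34a, a transcriptional target of p53, are annotated to chromosome 4, 149442584 to 149442603, also listed as minus. Those for miR-21 are annotated to chromosome 11, 86397622 to 86397641, listed as plus. Each of these is a miRNA locus, and the files give no further annotation of exon or intron. Whether the listed strand is that of the probe or of the miRNA was not checked.

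The first comparison asked which liver miRNAs differ 4 h after the last BaP dose, with each mouse counted once. No miRNA passed the test in 6 BaP against 6 control mice. The miRNA with the lowest p, miR-34a, which p53 induces after DNA damage, was 0.42 ± 0.19 higher on the log2 scale (1.34-fold), and 5 of 6 BaP mice lay above the control mean (adjusted p = 0.983). Over the alternatives its difference ran from 0.20 to 0.53 and its adjusted p from 0.454 to 1.00. Among miRNAs with roles in growth and lipid metabolism, miR-27a was higher by 0.24 ± 0.12 (5 of 6 mice), miR-23a by 0.15 ± 0.09 (6 of 6) and miR-24 by 0.14 ± 0.08 (5 of 6), each with an adjusted p of 0.983. In the other direction, miR-455 differed by -0.18 ± 0.08 (below the control mean in 6 of 6 mice) and miR-378, a regulator of metabolism, by -0.23 ± 0.11 (5 of 6), with the same adjusted p.

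Hepatocyte miRNAs lay near 0: 5 of 10 list members were higher and 5 lower in BaP mice, and 0 passed the test; 9 of 10 were higher with the percentile over all probes and 2 of 10 with quantile normalization. The difference was 0.04 ± 0.11 for miR-122, -0.03 ± 0.09 for miR-148a, 0.02 ± 0.13 for miR-192, 0.01 ± 0.09 for miR-194, 0.12 ± 0.20 for miR-802 and -0.04 ± 0.11 for miR-193. Of the p53 and DNA damage list, 6 of 7 members were higher, or 4 of 7 with quantile normalization, and 0 passed. Besides miR-34a these were led by miR-143 at 0.54 ± 0.37, while miR-16 (0.01 ± 0.10), miR-15a (0.05 ± 0.11) and miR-107 (-0.02 ± 0.08) lay near 0. All 4 tested leukocyte miRNAs were lower, with miR-146a, a brake on inflammatory signalling, at -0.14 ± 0.07 (5 of 6 mice) and miR-142-3p, a miRNA of all blood lineages, at -0.06 ± 0.15. The leukocyte list had a camera adjusted p of 0.0652 and an adjusted p = 0.824 with an estimated correlation. With normexp background correction all 4 were higher instead, and with the percentile over all probes 3 of 4 were lower.

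Red blood cell miRNAs were higher in 2 of 3 cases, with miR-144 at 0.08 ± 0.27 and miR-486 at -0.05 ± 0.12. Endothelial and mesenchymal miRNAs were higher in 4 of 7 cases and bile duct and epithelial miRNAs in 2 of 4, with miR-200b, an epithelial miRNA, at 0.39 ± 0.35 and miR-31 at -0.18 ± 0.11. In both lists BaP mouse 7 stood apart: its miR-200b lay 2.35 and its miR-143 lay 1.45 above the mean of the other 5 BaP mice in the ratio to pool. Without this mouse the BaP difference was 0.01 for miR-200b and 0.29 for miR-143. On 2 of 5 shorter and 2 of 6 longer stored BaP arrays miR-200b lay within 0.1 of the floor, so the size of its departure depends on the floor. In the growth and injury list 3 of 5 were higher, with miR-21 at -0.05 ± 0.14 and miR-221, which represses the cell cycle inhibitor p27, at -0.14 ± 0.10. The miR-29 and miR-30 families had 3 of 8 higher, or 8 of 8 with the percentile over all probes, with miR-29b, a repressor of collagens, at 0.22 ± 0.12 (6 of 6 mice). The let-7 family had 7 of 9 higher, or 4 of 9 with quantile normalization, with let-7e at 0.11 ± 0.15 and let-7g at -0.02 ± 0.09. The miR-17-92 family of proliferation miRNAs had 3 of 8 higher, or 8 of 8 with the percentile over all probes, with miR-92a at -0.11 ± 0.14 and miR-93 at 0.04 ± 0.07. The lipid metabolism list had 6 of 8 and the possible fragments 3 of 5 higher. The Dlk1-Dio3 cluster had 1 tested member, which was lower, and the muscle list and the brain and pancreas list had 0.

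By limma, 0 of 134 tested miRNAs passed and 2 (miR-34a and miR-455) had an unadjusted p under 0.05. Adjusted over the list alone, 0 members passed in every list. By camera, 0 of 12 tested lists passed at the preset correlation, and 0 passed with an estimated correlation or by fry. The 95% interval of the difference lay within 2-fold for 129 of 134 miRNAs (96.3%) and within 1.5-fold for 118 (88.1%). The leukocyte list passed camera as lower with quantile normalization, cyclic loess, the total signal per miRNA, the deposited log2 table, the lower floor, or only miRNAs detected on every array, and in 0 of these with an estimated correlation. The hepatocyte list passed camera as lower than the other miRNAs with normexp (adjusted p = 0.0206) and with no filter (adjusted p = 0.00613). With an estimated correlation it passed in neither (adjusted p = 0.899 and 0.366).

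**Figure D1:**
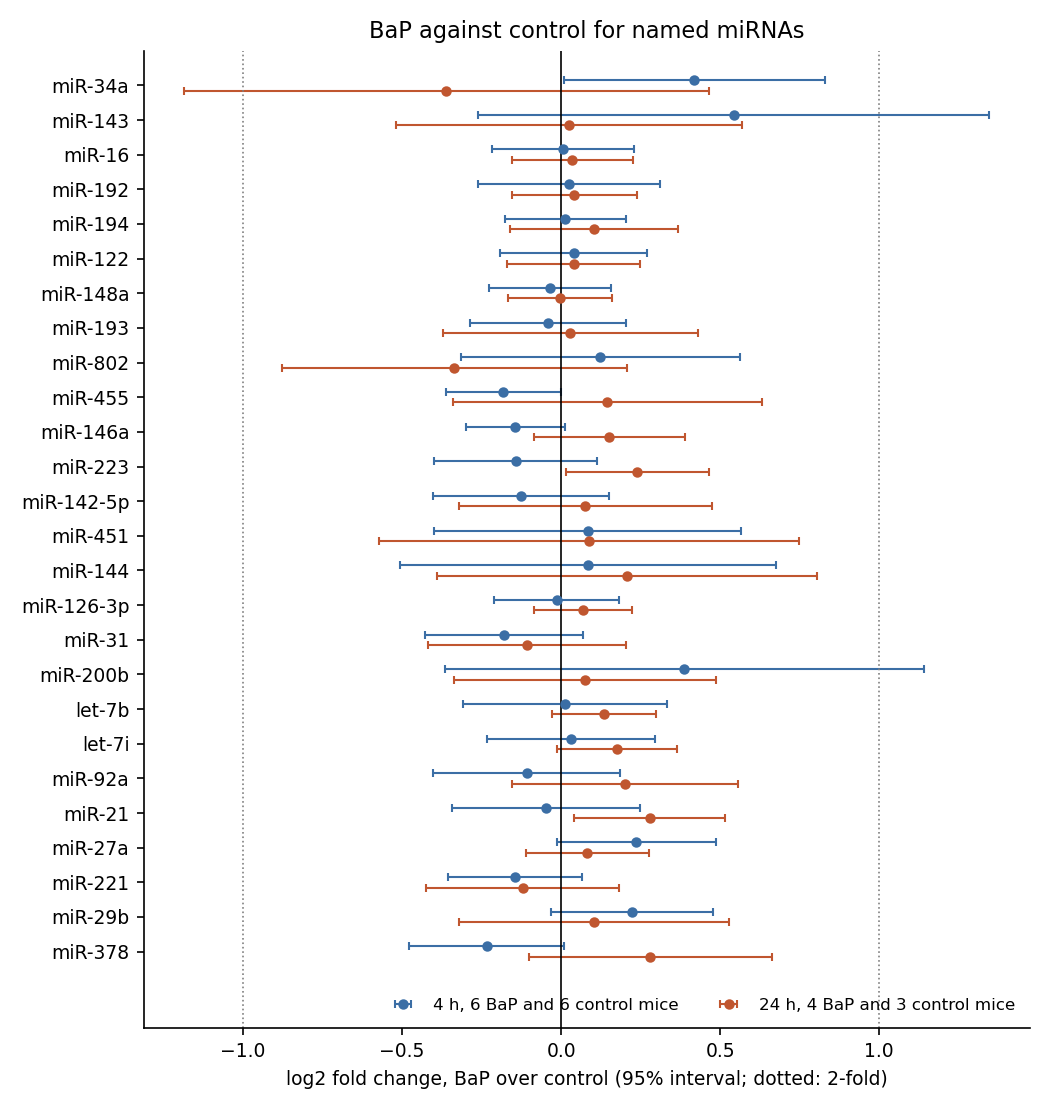
Log2 fold change of BaP over control for named miRNAs at 4 h (blue, 6 BaP and 6 control mice, mean of each animal's arrays) and 24 h (orange, 4 BaP and 3 control mice); points are limma estimates, bars 95% intervals, dotted lines mark 2-fold. At 4 h miR-34a stood at 0.42 and miR-122 at 0.04, and no miRNA passed the adjusted test at either time.

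In RNA stored for under 7 days (5 BaP and 6 control mice at 4 h), miR-34a was 0.37 ± 0.19 higher in BaP mice, from a log2 level of -3.71 ± 0.35 (SD, n = 6) in controls to -3.34 ± 0.35 (SD, n = 5). Several dim miRNAs were lower: miR-500 by -0.24 ± 0.08, miR-455 by -0.20 ± 0.07 (5 of 5 mice below every control), let-7f* by -0.41 ± 0.16, miR-290-3p by -0.38 ± 0.15 and miR-149 by -0.44 ± 0.18, each with an adjusted p of 0.756. The BaP means of the 3 last (-5.77, -5.80 and -5.76) lay near the floor of -5.85, so the sizes of these differences depend on the floor. The difference was 0.26 ± 0.16 for miR-27a, -0.31 ± 0.19 for miR-378 and -0.24 ± 0.14 for miR-223, a granulocyte miRNA. It was 0.68 ± 0.46 for miR-143 and 0.36 ± 0.42 for miR-200a, both high in BaP mouse 7, and without this mouse it was 0.48 and -0.13. For miR-122 it was -0.02 ± 0.12, for miR-21 -0.15 ± 0.17 and for miR-192 -0.08 ± 0.14. All 4 leukocyte miRNAs, all 3 red blood cell miRNAs, 8 of 8 of the miR-17-92 family, 7 of 9 of the let-7 family and 8 of 10 hepatocyte miRNAs were lower, on a median over all tested miRNAs of -0.06. These directions turned with the percentile over all probes, where that median was 0.19 and 4 of 4, 3 of 3, 8 of 8, 9 of 9 and 9 of 10 were higher. By limma, 0 of 133 miRNAs passed, with 8 at an unadjusted p under 0.05, and 0 lists passed. The interval lay within 2-fold for 128 miRNAs (96.2%) and within 1.5-fold for 102 (76.7%). Within slides that held both groups, the miR-34a difference was 1.07 on slide 5, -0.17 on slide 7 and 0.23 on slide 8.

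In RNA of the same mice stored for 6 to 8 weeks (6 against 6), miR-34a was 0.44 ± 0.24 higher (5 of 6 mice), miR-27a 0.23 ± 0.11 (6 of 6) and miR-29b 0.23 ± 0.12. For miR-378 the difference was -0.21 ± 0.12, for miR-455 -0.19 ± 0.13 and for miR-146a -0.15 ± 0.11. The adjusted p was 0.997 for each. The difference was 0.57 ± 0.44 for miR-143 and 0.44 ± 0.38 for miR-200b, or 0.27 and 0.03 without BaP mouse 7. It was 0.05 ± 0.16 for miR-122 and -0.04 ± 0.17 for miR-21. All 4 leukocyte miRNAs were lower here too (camera adjusted p = 0.126, adjusted p = 0.539 with an estimated correlation), but all 4 were higher with normexp background correction. The list passed camera as lower with cyclic loess, the total signal per miRNA and the deposited log2 values, but in none of them with an estimated correlation (adjusted p = 0.0838, 0.289 and 0.0973). The hepatocyte list passed camera as lower than the other miRNAs with normexp (adjusted p = 0.0122) and with no filter (adjusted p = 0.0163). With an estimated correlation it passed in neither (adjusted p = 0.742 and 0.344). Of the hepatocyte list 7 of 10, of the p53 list 6 of 7 and of the let-7 family 9 of 9 were higher, or 2 of 10, 4 of 7 and 5 of 9 with quantile normalization. By limma, 0 of 136 miRNAs passed, with 0 at an unadjusted p under 0.05, and 0 lists passed. The interval lay within 2-fold for 129 (94.9%) and within 1.5-fold for 114 (83.8%). Within slides, the miR-34a difference was 0.16 on slide 10, 0.78 on slide 11 and 0.49 on slide 12.

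The 2 sets of arrays came from the same mice, so that their BaP differences share the differences between animals. Across 128 miRNAs, which are not independent replicates, these differences correlated with r = 0.748 and rho = 0.741, with the same sign in 85 (66.4%). Over 100 groupings of the animals, the real one included, 2 gave an r as high, and the others had a median r of 0.364 and ran from -0.41 to 0.75. Across the 11 animals with both arrays, the miR-34a ratio to pool correlated between the arrays with r = 0.840 (permutation p = 0.00118) and rho = 0.827 (permutation p = 0.00287), and r was 0.757 without the 2 animals farthest from the median. An exact permutation test over the 924 groupings of the 12 mice gave p = 0.0844 for the miR-34a signal and p = 0.0563 for its ratio to pool, where the difference was 0.40. These 2 tests on miR-34a and the correlation were chosen after its values were seen.

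**Figure D2:**
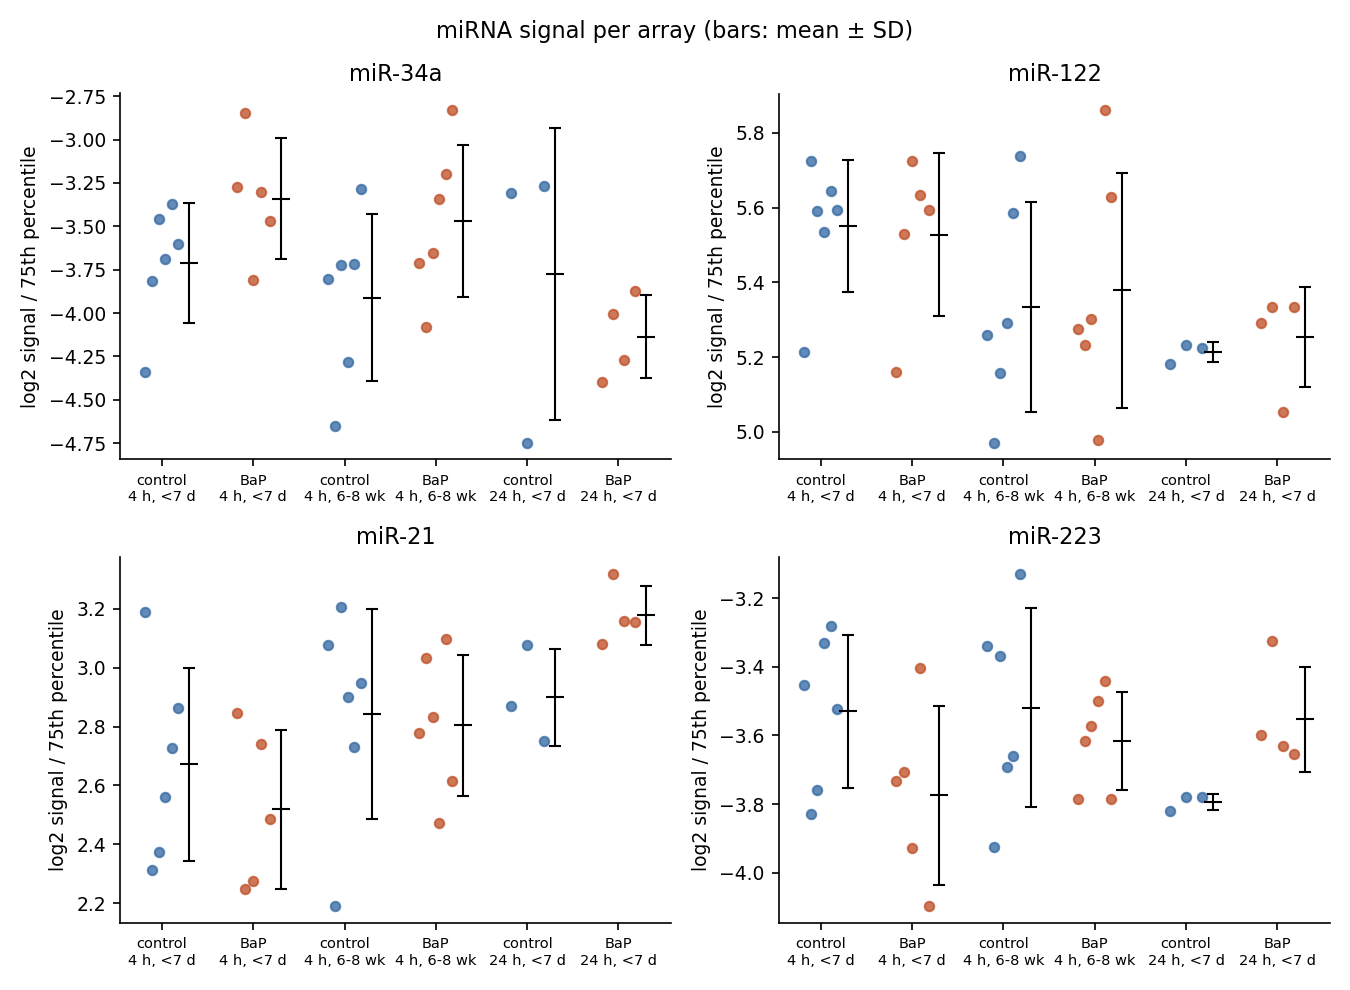
Log2 signal relative to the array's 75th percentile for miR-34a, miR-122, miR-21 and miR-223 on each animal's array, by treatment, time and RNA storage (points are arrays, bars mean and SD). In RNA stored for under 7 days at 4 h, miR-34a averaged -3.71 in controls and -3.34 in BaP mice, with overlapping values.

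The 24 h comparison asked which miRNAs differ a day after the last dose (4 BaP against 3 control mice, all on 1 slide). No miRNA passed the test. The bright miRNA miR-21, linked to liver growth and injury, was 0.28 ± 0.10 higher (1.21-fold), and miR-223, a granulocyte miRNA, was 0.24 ± 0.10 higher. In each case 4 of 4 BaP mice lay above every control (adjusted p = 0.981). Without scaling the difference was -0.46 for miR-21 and -0.50 for miR-223, and with normexp background correction it was 0.35 and -0.81. Next were let-7i at 0.17 ± 0.08 and let-7b at 0.14 ± 0.07, also above every control in 4 of 4 mice. In the other direction miR-197, which lies close to the floor and was detected on 3 of 7 arrays, differed by -0.84 ± 0.28 (4 of 4 below the control mean). The p53 target miR-34a was not higher: it differed by -0.36 ± 0.35, with 0 of 4 BaP mice above the control mean and a control SD of 0.84 (n = 3).

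All 4 tested leukocyte miRNAs were higher at 24 h, with miR-142-5p at 0.08 ± 0.17 beside miR-223, but all 4 were lower without scaling or with normexp background correction. The list had a camera adjusted p of 0.0885 and an adjusted p = 0.450 with an estimated correlation, and it passed camera with quantile normalization and cyclic loess, but in neither with an estimated correlation (adjusted p = 0.281 and 0.342). Without scaling 0 members of any list were higher at 24 h, with a median shift of -0.74. In the main scaling hepatocyte miRNAs had 6 of 10 higher, or 4 of 10 with quantile normalization: miR-122 at 0.04 ± 0.09, miR-192 at 0.04 ± 0.08, miR-148a at 0.00 ± 0.07, miR-101b at 0.07 ± 0.12, miR-193 at 0.03 ± 0.17, miR-455 at 0.15 ± 0.21 and miR-802, detected on 3 of 7 arrays, at -0.34 ± 0.23. Of the p53 list 5 of 7 were higher, or 2 of 7 with quantile normalization, with miR-194 at 0.10 ± 0.11, miR-16 at 0.03 ± 0.08, miR-15a at 0.00 ± 0.09 and miR-143 at 0.03 ± 0.23. The miR-29 and miR-30 families had 7 of 8 higher, or 3 of 8 with normexp, led by miR-30d at 0.30 ± 0.16. The let-7 family had 4 of 9, the miR-17-92 family 4 of 8 and the growth and injury list 3 of 5 higher, with miR-92a at 0.20 ± 0.15. Both tested red blood cell miRNAs were higher, with miR-451 at 0.09 ± 0.28 and miR-144 at 0.21 ± 0.26. The mesenchymal list had 5 of 6, the epithelial list 2 of 4 (miR-200b at 0.08 ± 0.18, miR-31 at -0.11 ± 0.13), and lipid metabolism 4 of 7 (miR-378 at 0.28 ± 0.16). Possible fragments were higher in 5 of 6 cases, with miR-720 at 0.53 ± 0.36 and miR-721 at -0.61 ± 0.42, and the 1 tested Dlk1-Dio3 member was higher. Among other miRNAs, miR-22 stood at 0.29 ± 0.15, miR-1224 at 0.39 ± 0.19 and miR-467b* at -0.58 ± 0.34.

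By limma, 0 of 115 miRNAs passed at 24 h and 3 (miR-21, miR-223 and miR-197) had an unadjusted p under 0.05, and 0 lists passed. Adjusted over the list alone, 0 members passed in every list. The interval lay within 2-fold for 108 miRNAs (93.9%) and within 1.5-fold for 95 (82.6%). A block for the numbers shared by a control and a BaP mouse, which leaves 2 pairs and 1 residual degree of freedom, gave 2 miRNAs past the threshold, both lower (miR-197 at -0.90 ± 0.25 and miR-721 at -0.87 ± 0.25).

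The next comparison asked whether the BaP effect differed between 24 h and 4 h. No miRNA passed the test of that difference. It was -0.78 ± 0.28 for miR-197, 0.48 ± 0.20 for miR-223, 0.32 ± 0.14 for miR-146a, which restrains inflammatory signalling, and 0.17 ± 0.08 for miR-342-3p, each with an adjusted p of 0.770. With normexp background correction all of these were negative (-0.68 for miR-223), as was miR-455 (0.35 ± 0.20). For miR-34a the effect was -0.73 ± 0.41 at 24 h relative to 4 h, for miR-378 0.59 ± 0.29 (-0.48 with normexp, -0.23 without scaling), for miR-21 0.43 ± 0.24 (-0.38 without scaling), for miR-145 -0.46 ± 0.25 and for miR-122 0.06 ± 0.16. Within 0.1 of the floor lay miR-342-3p on 5 of 5 BaP arrays at 4 h and 4 of 4 at 24 h. So did miR-145 on 6 of 6 control arrays at 4 h, and the sizes of both differences depend on the floor. Of the leukocyte list 4 of 5, of the hepatocyte list 8 of 10, of the p53 list 5 of 8 and of the miR-17-92 family 7 of 9 had positive differences, and without scaling 0 of each did. By limma, 0 of 154 miRNAs passed, with 4 at an unadjusted p under 0.05, and 0 lists passed. The interval lay within 2-fold for 123 and within 1.5-fold for 83. Without control mouse 11 of the 24 h group 1 miRNA passed, miR-720 at 1.05 ± 0.21, and with normexp correction 98 passed, all negative, on a median shift of -0.95. Across miRNAs the 24 h effects did not follow those at 4 h (r = -0.18 over 111 miRNAs).

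Storage was studied by comparing RNA stored for 6 to 8 weeks with RNA stored for under 7 days from the same 11 mice. Of 134 tested miRNAs 3 rose and 0 fell. A sequence on the list of possible fragments of longer RNAs, miR-690, rose by 0.89 ± 0.19 (higher in 9 of 11 mice, adjusted p = 0.0358), and miR-709 of the same list by 0.58 ± 0.13 (10 of 11, adjusted p = 0.0358). The epithelial and hepatocyte miRNA miR-194 rose by 0.28 ± 0.07 (11 of 11, adjusted p = 0.0388). The pooled RNA, 1 RNA labelled as stored for 6 to 8 weeks, shifted with them. Between the slides of longer stored RNA and the other slides its miR-690 differed by 1.07, its miR-709 by 0.38 and its miR-194 by 0.34. Whether the pool itself aged between these slides was not tested, and ageing could cancel a storage effect in a ratio to it. In the ratio to the pool arrays of the same slide 0 miRNAs passed by limma, with 29 at an unadjusted p under 0.05. There the change was -0.08 ± 0.10 for miR-690, -0.03 ± 0.05 for miR-194 and 0.21 ± 0.06 for miR-709 (adjusted p = 0.103; 0.000167 to 0.958 over all alternatives).

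Other miRNAs stopped short of the threshold, and their signal alone cannot tell storage from slide either. Higher in the longer stored RNA were miR-126-5p, an endothelial miRNA, at 1.45 ± 0.42, miR-142-3p at 0.70 ± 0.25, miR-30c at 0.63 ± 0.21, miR-143 at 0.57 ± 0.23, miR-101b at 0.54 ± 0.17, miR-203 at 0.52 ± 0.16, miR-98 at 0.41 ± 0.11, miR-221 and miR-101a at 0.37 ± 0.10 and 0.37 ± 0.12, miR-802 at 0.30 ± 0.11 and miR-16 at 0.27 ± 0.11. Lower were let-7b at -0.45 ± 0.14, let-7i at -0.34 ± 0.10, miR-22 at -0.33 ± 0.11, miR-92a at -0.32 ± 0.12, miR-15a at -0.23 ± 0.09 and miR-122 at -0.23 ± 0.10. The difference was 0.20 ± 0.11 for miR-21, -0.19 ± 0.09 for miR-34a, 0.28 ± 0.18 for miR-144, -0.15 ± 0.10 for miR-451, -0.02 ± 0.07 for miR-192 and 0.00 ± 0.06 for miR-720. In the ratio to pool miR-126-5p stood at -0.11, where the pool itself shifted by 1.53, miR-30c at 0.02, miR-142-3p at 0.19, miR-98 at 0.28, let-7b at -0.06, let-7i at 0.01, miR-92a at 0.06, miR-15a at 0.10, miR-122 at 0.02 and miR-34a at 0.16. For miR-98 the pool shifted by only 0.15, and its change in the ratio had a standard error of 0.07 and a limma adjusted p of 0.103. Of the let-7 family 8 of 9 members were lower in the signal, or 6 of 9 without scaling, and 8 of 9 were higher in the ratio to pool (camera on the signal adjusted p = 0.0780, adjusted p = 0.803 with an estimated correlation). The fragment list passed fry (adjusted p = 0.00801, 3 of 5 higher, 2 past the threshold) but not camera, and no other list passed either test. In the ratio to pool this fry call was lost (adjusted p = 0.559). Adjusted over the list alone, the members past the threshold were 5 of the p53 list, 4 of the hepatocyte list, 2 of the leukocyte list, 5 of the let-7 family, 4 of the miR-17-92 family, 5 of the miR-29 and miR-30 families, 3 of the fragments, and 1 each of the mesenchymal, epithelial, growth and injury, and lipid lists. These counts are of the signal, and in the ratio to pool they were 2 of the let-7 family, 1 of the hepatocyte list, 1 of the fragments and 0 of every other list. By limma 59 of 134 had an unadjusted p under 0.05. The interval lay within 2-fold for 129 and within 1.5-fold for 116. The probes of 41 of the 134 miRNAs did not share a sign. The count depended on the mouse left out: it was 65 without BaP mouse 6, 49 without control mouse 7, 29 without control mouse 5 and 0 without any other 1 of the 11. The 3 mice whose removal raised it are those of the 11 with an array on slide 12.

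**Figure D3:**
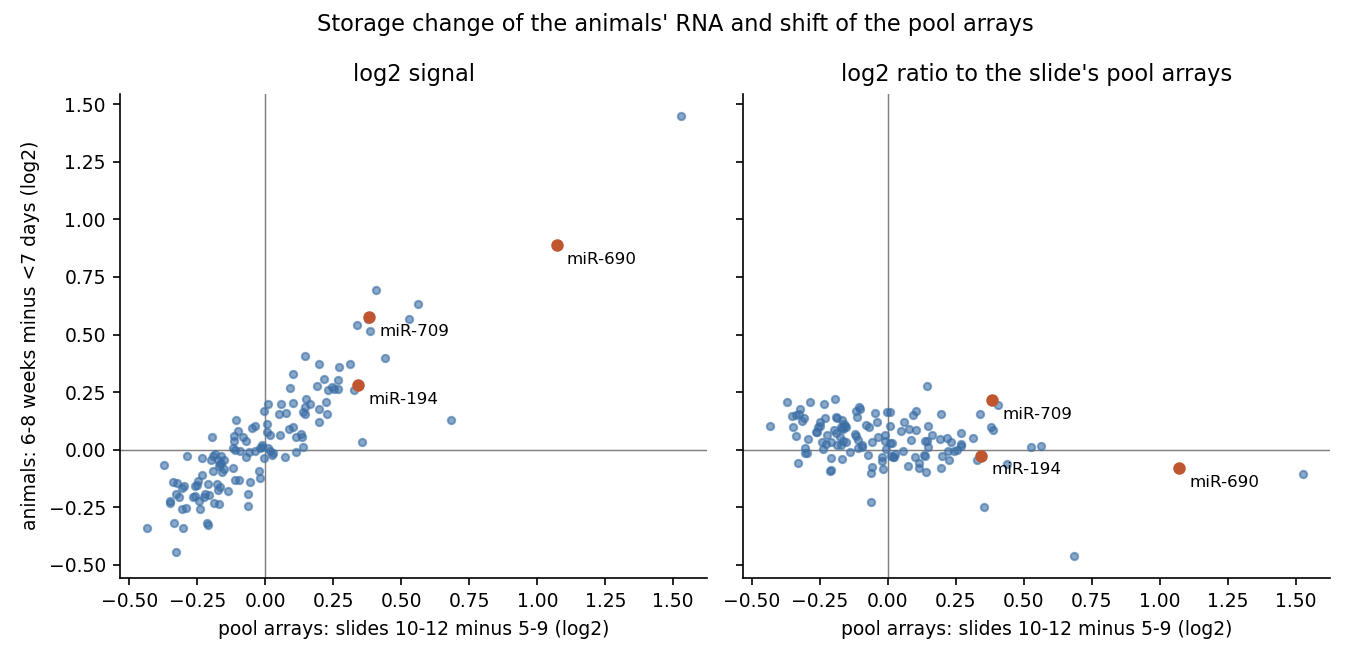
Log2 change of 134 miRNAs from RNA stored for under 7 days to RNA stored for 6 to 8 weeks (vertical axes, 11 mice) against the shift of the pooled RNA between the same slides (horizontal axes), for the signal (left) and the ratio to the slide's pool arrays (right); orange points are the 3 miRNAs past the test. On the left miR-690 rose by 0.89 where the pool shifted by 1.07, and on the right its change was -0.08.

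Whether storage altered the BaP effect was asked within animals. No miRNA passed the test. The BaP effect in longer stored minus shorter stored RNA was 0.01 ± 0.20 for miR-34a, -0.03 ± 0.21 for miR-122, 0.10 ± 0.14 for miR-194, 0.19 ± 0.39 for miR-690, 0.20 ± 0.21 for miR-451, -0.24 ± 0.18 for miR-1224 and -0.29 ± 0.28 for miR-494. All 4 leukocyte miRNAs, all 7 mesenchymal miRNAs and all 9 let-7 miRNAs had positive differences, but with the percentile over all probes, which moved the median of all by -0.25, 0 of 4, 1 of 7 and 0 of 9 did. By limma, 0 of 136 miRNAs passed, with 0 at an unadjusted p under 0.05, and 0 lists passed. The interval lay within 2-fold for 128 and within 1.5-fold for 101.

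The spread of the pooled RNA over its 12 arrays had a median SD of 0.213 on the log2 scale. The median SD between mice at 4 h was 0.204 in controls (n = 6) and 0.207 in BaP mice (n = 5) with RNA stored for under 7 days, and 0.255 and 0.241 with longer stored RNA (n = 6 each). On the 4 slides with 2 pool arrays it was 0.0772. Between mice at 24 h, on 1 slide, it was 0.127 in controls (n = 3) and 0.126 in BaP mice (n = 4). All these SDs were taken over the 134 miRNAs tested with animal means at 4 h. Only 115 miRNAs were tested at 24 h, and values at the floor spread little. The 24 h SDs therefore cannot be set against those at 4 h. The first principal component of the 89 miRNAs detected on every array held 33.5% of the variance, and the slide accounted for 98.8% of it among the 4 h arrays, pool arrays included. Among the 4 h arrays of animals alone storage accounted for 23.3% and BaP for 0.126%. In the ratio to pool, 8 of 11 mice had their own second array as their best match, against 5 of 11 in the signal, with a median r of 0.619 between an animal's arrays across miRNAs. This r ran from -0.08 for control mouse 5, whose arrays share a slide, and 0.16 for BaP mouse 6 to 0.93 for BaP mouse 7. Over the 7 comparisons 82 list tests were run, of which 0 passed camera at the preset or the estimated correlation, 11 had an unadjusted p under 0.05, and 1 passed fry.

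**Figure D4:**
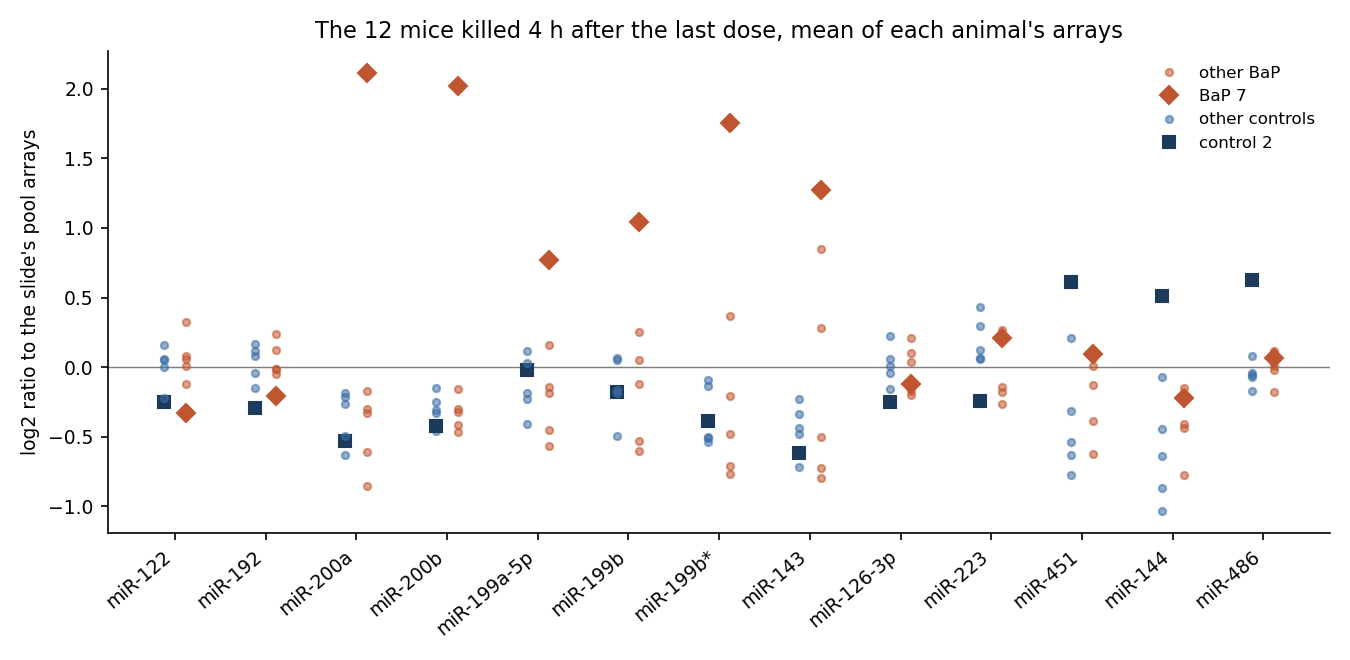
Log2 ratio to the slide's pool arrays of 13 miRNAs of hepatocytes, epithelium, mesenchyme, endothelium, granulocytes and red blood cells in the 12 mice killed at 4 h (points are the mean of each animal's arrays). BaP mouse 7 (diamonds) lies above all other mice for miR-200a and miR-200b, and control mouse 2 (squares) for miR-451 and miR-144.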

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

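The counts over other groupings were planned, and the tests on storage, miR-34a, BaP mouse 7 and control mouse 2 and the checks of single arrays against the floor and the pool were chosen after those results were seen. For each named miRNA and each animal group of 4 to 6 arrays, the most extreme array was compared with the nearest of the others by Dixon's ratio (285 tests), as were the totals of the arrays and the departures of the animals (12 tests). In all, 29 of 297 tests, each of a miRNA, pointed to an array apart from its group. Chance gives about 1 in 20 for independent values without slide shifts or a floor, but these values have both: in 11 of the 29 the rest of the group lay within 0.1 of the floor, where any value above it stands apart, and of the 25 at 4 h only 8 also stood apart in the ratio to pool, 4 of them at the floor and 4 of them miR-200a and miR-200b of BaP mouse 7. In control mice at 4 h with RNA stored for under 7 days, mouse 6, the only control on its slide, stood apart for let-7b (0.0508, nearest 0.63), let-7e (-3.88), miR-101a (-0.31), miR-122 (5.21, nearest 5.54), miR-145 (-5.83), miR-193 (-0.54) and miR-92a (-2.09), and mouse 5 for miR-467b* (-5.28). Of those of mouse 6, only miR-145, at the floor, also stood apart in the ratio to pool. In BaP mice with the same storage, mouse 7 stood apart for miR-200a (-3.05, nearest -5.12), miR-200b (-3.49, nearest -5.58) and miR-690 (-4.99, nearest -4.59). Near the floor, mouse 6 stood apart for miR-197 (-5.47) and miR-467b* (-4.86), mouse 3 for miR-290-3p (-5.64) and mouse 2 for miR-342-3p (-5.79). In control mice with longer stored RNA, mouse 2 stood apart for miR-193 (-1.70) and miR-486 (-5.24), mouse 7 for miR-290-3p (-4.47) and miR-342-3p (-5.43), and mouse 1 for miR-467b* (-5.31). In BaP mice with longer stored RNA, mouse 7 stood apart again for miR-200a (-2.73, nearest -5.22) and miR-200b (-3.17, nearest -5.26), mouse 2 for miR-197 (-5.12) and miR-467b* (-5.81), and mouse 5 for miR-342-3p (-5.59). In BaP mice at 24 h, mouse 11 was lowest for miR-122 (5.05, nearest 5.29), mouse 10 highest for miR-223 (-3.33, nearest -3.60), and mouse 9 highest for miR-342-3p (-5.79) and miR-467b* (-5.09).

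Other groupings of the same animals were counted for every comparison. With a real count of 0 every grouping gives as many, so these counts say nothing about chance: 100 of 100 for BaP at 4 h with each storage class and with animal means (highest others 33, 38 and 1), 35 of 35 at 24 h (real 0, highest other 2), and 100 of 100 for the difference in BaP effect between storage classes and between times (real 0, highest others 48 and 31). The grouping with 38 miRNAs points to a structure of the arrays: it put all 4 arrays of slide 12 on one side, and animal means, which average over slides, reached 1 at most. The slides in the grouping with 48 were not examined. For storage 1 of 100 gave as many, the real one alone (real 3, highest other 0), which is the fewest possible. Exchanging a mouse's arrays also exchanged their slides, except for control mouse 5, so this count cannot tell storage from slide.

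The first pattern is the rise of miR-690, miR-709 and miR-194 in longer stored RNA. All of that RNA was read on 3 slides and a scanner that held only 1 array of shorter stored RNA, and across the 134 miRNAs the storage change followed the shift of the pooled RNA between the same slides with r = 0.906, which is consistent with slide and scanner as the source. Against storage itself, miR-690 and miR-194 had a median change of -0.0527 in the ratio to pool, where at least 50% of the rise was needed. This takes the pooled RNA, itself labelled as stored for 6 to 8 weeks, as unchanged between slides, which was not tested. For miR-709 the ratio kept 0.21 (± 0.06) of a rise of 0.58 (± 0.13), so that storage and slide cannot be told apart for it, and longer storage may act on it. Only control mouse 5 has arrays of both labels on 1 slide. There the longer stored array was higher by 0.19 for miR-709, 0.32 for miR-690 and 0.04 for miR-194. Some other miRNAs differed far more between these 2 arrays, in both directions (miR-451 by -1.11, miR-144 by -1.06, miR-494 by 1.62, miR-1224 by 0.81). Differences as small as those of the 3 miRNAs therefore cannot be assigned to storage. Across the 134 miRNAs the change in this mouse correlated with the storage change with r = 0.10. The label of its shorter stored array, among arrays of longer stored RNA, is in doubt. In simulated data with slide shifts and no storage effect, the signal gave 54.7 false calls per run and the ratio to pool 2.15. The sizes of these shifts were set and not fitted to these data, where the signal gave 3 calls. The simulation thus shows only that slide shifts can give false calls, not that they did here.

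The second pattern is miR-34a, higher in BaP mice at 4 h in both sets of arrays without passing the test. Noise of single arrays is argued against, since the animals kept their order between independent arrays (r = 0.840 over 11 mice). Chance assignment of the animals stays open, with an exact permutation p of 0.0563 over the 12 mice in the ratio to pool. A p53 response to BaP is the biological explanation that the design offers, and it may be a weak one of about 1.34-fold; at 24 h, where BaP mice lay lower (-0.36 ± 0.35), it was not seen.

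The third pattern is BaP mouse 7, whose miRNAs departed from the mean of the other 5 BaP mice by a root mean square of 0.466 in the ratio to pool; the other mice departed from the rest of their own group by 0.175 to 0.317, where the rest of the BaP group includes mouse 7. A faulty array or slide is argued against, as its departures on 2 slides correlated across miRNAs with r = 0.933. A lower share of hepatocytes alone is argued against, since it would raise the markers of every other cell type alike, and the mesenchymal median lay 1.08 above the leukocyte median, while hepatocyte miRNAs were lower by a median of -0.34 and miR-122 by -0.40. More mesenchymal tissue in the piece may account for part of it, a hypothesis formed and tested on these same values. The endothelial and mesenchymal median was 1.01 (SD of the other mice 0.277, 5 of 7 higher), with miR-199b* at 2.11, miR-143 at 1.45 and the endothelial miR-126-3p at -0.12. This leaves the rise of the epithelial miRNAs miR-200a and miR-200b unexplained. More bile duct epithelium stays open, because 2 of 4 epithelial miRNAs were higher (miR-200a by 2.57, miR-200b by 2.35) and 2 were not. These sizes depend on the floor. Within 0.1 of it lay miR-200b on 2 of 5 BaP arrays with shorter and 2 of 6 with longer stored RNA, and miR-200a on 1 of 5 and 1 of 6. A response of this one mouse to BaP was not tested, and the series description says that liver sections were taken at random.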

How the results depend on the processing

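The 132 named fold changes were recomputed under the alternatives as 3642 values, of which 3335 kept their sign and 307 did not. Some alternatives, such as the trended prior, leave the estimate and so its sign unchanged. Of these values 40 dropped below the threshold, 125 passed it, and 9 reversed. Only the 3 storage calls could drop. Past the threshold stayed miR-194 in 13 of 29 alternatives, miR-690 in 13 of 28 and miR-709 in 14 of 29. The scaling of the arrays is a limit: scaling to the 75th percentile over all probes moved the median of all miRNAs by 0.26 (4 h, RNA stored for under 7 days), 0.11 (animal means), 0.52 (24 h), -0.15 (storage), -0.25 (BaP by storage) and 0.26 (BaP by time), no scaling by -0.74 (24 h), 0.19 (storage), 0.16 and -0.80, normexp by 0.23 (4 h, longer stored), 0.11, -0.75 (24 h), 0.24 and -0.95, and the total signal per miRNA by -0.14 (storage). BaP at 4 h gave 0 miRNAs in every alternative run, the block for shared numbers and each left-out replicate (0 to 0) included. BaP at 24 h gave 0 except with the replicate block (2 miRNAs, a pairing that leaves 1 degree of freedom); leaving out a replicate gave 0 to 0. An alternative chosen after seeing the data, without the 3 dimmest arrays, also gave 0. The storage count of 3 became 19 with quantile normalization, 38 with cyclic loess, 30 with the brightest probe, 37 with the total signal per miRNA, 6 with the deposited log2 table, 7 with a floor at 1% and 26 with no replicate block. It became 0 with the percentile over all probes, no scaling, normexp, no filter, the ratio to pool, a slide term and a scan day term with the pool arrays, and 0 to 65 leaving out 1 replicate. Without the 3 animals with an array on slide 12, an alternative chosen after seeing the data, it was 79. These are the same 3 mice whose single removal raised the count. In the ratio to pool, with a slide term and with a scan day term, miR-690 became -0.0798, -0.0388 and -0.0312 and miR-194 became -0.0255, -0.0310 and -0.0388. The pool itself shifted by 1.07 for miR-690 and 0.34 for miR-194. These alternatives take the pool as unchanged between slides, which was not tested. The BaP by storage count stayed 0 (0 to 0 leaving out 1 replicate). The BaP by time count became 98 with normexp, and 0 to 1 leaving out 1 replicate; under normexp miR-146a became -0.84, miR-342-3p -1.14 and miR-455 -1.10. The 0 list tests past the threshold became 1 with fry, 2 with quantile normalization, 3 with cyclic loess, 8 with normexp, 2 with the total signal, 2 with the deposited table, 1 with the lower floor, 2 with detection on every array and 29 with no filter, which adds miRNAs at the floor, and 0 with an estimated correlation. The pool spread became 0.381 with the percentile over all probes and 0.369 without scaling. Of 518 intervals for BaP, 494 (95.4%) lay within 2-fold, against 369 (71.2%) without scaling, 378 (73.0%) with the percentile over all probes and 391 (75.5%) with normexp, so this bound depends on the scaling. Without a filter 2226 of 2268 did, as more miRNAs were tested. These totals pool the 24 h fit with the 3 fits at 4 h, which share the same 12 mice, so the intervals are not independent. Where no cause is given, the cause was not tested. A scan day block was not run for animal means and BaP by storage, nor for 24 h (1 day), where it cannot be fitted, and lists were not recomputed without single animals. In simulated data without slide effects, 83.5% of 1.5-fold and 94.5% of 2-fold changes were recovered with animal means at 4 h (134 miRNAs), 80% of 1.5-fold and 89% of 2-fold at 24 h (115), and 93% of 1.5-fold for storage (134); recovery of 1.5-fold was lower at 4 h with shorter (72.5%) and longer stored RNA (70.5%), for BaP by storage (61%) and for BaP by time (58.5%). Each run changed 10 miRNAs at each of the folds 1.5, 2 and 3 together, and so many changes loosen the adjusted threshold. Recovery of a response of fewer miRNAs was not simulated.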

Other observations

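Control mouse 2 carried more of the miRNAs of red blood cells than the other control mice at 4 h. Above the mean of the other 5 control mice, in the ratio to pool, miR-451 was higher by 1.08 on its array with RNA stored for under 7 days and by 0.97 on the other, miR-144 by 1.21 and 1.04, and miR-486 by 0.67 and 0.68. With longer stored RNA miR-486 lay within 0.1 of the floor on 3 of 6 control arrays, so the size of that difference depends on the floor. More blood left in the piece may be the reason, a hypothesis formed and tested on these data: the red blood cell median was 1.03 (SD of the other mice 0.345, 3 of 3 higher), yet the leukocyte median was -0.16 and miR-223, of the granulocytes in blood, stood at -0.34 and -0.54, so the question stays open.

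In BaP mouse 7 further miRNAs, chosen after their values were seen, were higher than the mean of the other 5 BaP mice in the ratio to pool: miR-195 by 0.68, miR-125b-5p by 0.64, let-7e by 0.58 and miR-100 by 0.55.

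One probe set for a mouse herpesvirus miRNA, mghv-miR-M1-2, was above background on 40 of 42 arrays, controls and pool included, at a median intensity of 15.4, while the other 9 viral miRNAs were detected on 0 arrays.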
